A study of Arabidopsis thaliana with 59 samples.

How the data were processed

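Gene expression was measured in rosette leaves of Arabidopsis thaliana from 10 accessions that flower as spring annuals (Ws-2, Bur-0, Ts-1, CIBC-17, HR-5, KNOX-18, NFA-10, SQ-8, Ler and Col) under 2 watering levels. Per the labels' protocols, plants stood singly in pots with about 150 ml of a porous ceramic medium, under a 10 h photoperiod at 330 µmol m-2 s-1, with 23 C by day, 18 C by night and 60% relative humidity. Wet pots were held near 90% of water remaining, and dry pots were let down in daily steps from 90% to about 50% by day 5, with weighing before dawn. Leaves went into RNAlater, RNA was taken with a Qiagen plant kit, and biotin-labelled cRNA was made with a MessageAmp II protocol, per the labels' protocols. The labels number 3 biological replicates in each of the 20 groups of accession and watering, except that KNOX-18 dry has replicates 1 and 3 only, so 59 arrays entered the work (30 wet and 29 dry).

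The deposited table holds 1 value per locus and array on a log2 scale, from 3.066 to 14.06, for 20728 loci. The submitters' processing notes name MAS5 and RMA, without versions and without saying which of them made which step. The array platform and the assignment of probes to loci are not given in the sources used here. Array medians lay between 5.496 and 5.621, so the arrays had been brought close to one another, and the values were used as deposited. No column of the table was left unused, and 0 arrays held the same values as another. The test plan had assumed probe sets. Since the table gives loci, the choice among probe sets of a gene, and the alternative that averages them, did not apply, and neither did the alternative for values on a linear scale. Values from arrays carry no read depth, so the number of arrays limits the precision, and loci near the bottom of the scale cannot be told from background.

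Loci were named through a table of reference genes of the assembly TAIR10.1, which held 20546 of the 20728 loci; the remaining 182 kept their locus names. The build behind the array is not named, so no coordinates are given. In 14 cases a locus had the same values as another locus on every array; these were tested but were left out of the gene lists and of the named genes.

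A linear model with 1 mean for each of the 20 groups was fitted to each locus with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 39 residual degrees of freedom, 1.962 prior degrees of freedom). All groups shared the estimate of the spread. From this fit came the mean over accessions of dry minus wet, dry minus wet in each accession, a moderated F test among the 10 accession means, a moderated F test of dry minus wet among accessions (the interaction), and each accession against Col. P-values were adjusted by the Benjamini-Hochberg method over all loci within each contrast, and the threshold was an adjusted p of 0.05. Gene lists were compared with all other loci by camera from limma with a preset correlation of 0.01 between genes, and again with an estimated correlation. The rotation test fry, which asks whether the genes of a list move one way and does not set the list against other genes, served as an alternative. In addition, the mean of a list's members was taken per array and differenced between dry and wet in each accession, and these 10 differences were put to a two-sided exact sign-flip permutation test with 1024 sign patterns, whose smallest possible p is 0.00195. Whether a list's shift differed among accessions was tested by permuting residuals among accessions within watering level and replicate number, with 1e-04 as the smallest p these permutations can give.

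The 30 gene lists held 534 members, of which 9 were left out because their symbol was not matched and 473 were measured, from 5 to 29 in a list. The lists were dehydration and ABA induced genes, ABA core signalling, proline metabolism, galactinol with starch and sugar, photosynthesis and light harvesting, Calvin cycle, expansins and cell wall, aquaporins, salicylate defence, jasmonate and wounding, glucosinolate synthesis, flavonoids and anthocyanins, heat shock proteins, reactive oxygen scavenging, circadian clock, cold and CBF regulon, auxin response, cytokinin response, gibberellin and brassinosteroid, nitrogen and amino acids, cell cycle, leaf senescence, guard cell markers, vascular markers, trichome and epidermis markers, root markers, floral markers, known natural variation, housekeeping genes and cytosolic ribosomal proteins. The named genes followed a fixed rule: for drying, the 10 largest rises and the 10 largest falls among genes past the threshold with 1 sign in all 10 accessions; for the interaction, the 12 smallest p-values; among accessions, the 12 largest ranges of means past the threshold; from each list, at most 6 members with the smallest adjusted p; and a short set of genes known from drought and natural variation work (RD29A, RD29B, RAB18, NCED3, HAI1, FLC, ESM1, PHYD and PR1; P5CS1, AOP2, AOP3 and MAM1 from that set were not analysed here). A few further list members, named for their place in a list, were chosen after their values were seen. The groups, the tests, the lists, this rule and the alternatives other than those described as added were fixed before the data were examined.

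Replicate numbers recur in every group, and whether they pair the arrays was checked on the deviations of each array from its group mean. Averaged over accessions, the deviations of wet and dry arrays with the same number correlated across genes at r = 0.61, 0.13 and 0.71 for numbers 1, 2 and 3, each above the limit of 0.1 set for pairing, so the numbers were taken to mark shared conditions and blocked values are given where they change a call or move a count by more than 1.5 times. Within single accessions, 24 of 29 wet and dry pairs exceeded 0.1, with a range from -0.2 to 0.564. The first principal component of the deviations carried 33.9% of their variance and put all 20 arrays of number 1 on one side and all 20 of number 3 on the other. The labels do not say what the numbers stand for. One label conflict was found: Col wet replicate 3 carries the stock number of Ws-2. It was kept as Col, was left out in an alternative, and lay nearest to the other Col arrays over the 300 genes that separate accessions best.

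The limma fits, camera with the preset correlation and the sign-flip test were tried on simulated data built on the real group structure with 20728 genes. The drying contrast recovered 94.03% of genes changed by 0.5 on the log2 scale and 100% of those changed by 1, with 0.0689% of unchanged genes called. The accession test recovered 92.54% of genes in which 1 accession differed by 1, with 5.5% of unchanged genes called. Most other simulated genes kept the accession means estimated from the data, whose scatter adds differences among accessions. This can loosen the adjusted threshold, so these accession rates need not hold in the data. For the interaction, 47.76%, 80.6% and 98.48% were recovered when 1 accession responded by 1, 2 or 4, with 0.039% of unchanged genes called. For lists, camera and the sign-flip test called 0 of 30 unchanged lists and 5 of 5 shifted lists. The simulated genes varied independently and carried no effect of replicate number. In the data the estimated correlation between members was 0.753 in the light harvesting list, so these list rates need not hold there. Alternatives covered array scaling (medians centred, quantile normalization), leaving out loci under the 30th percentile of mean value, leaving out loci without 1 gene of their own, replicate number as a fixed or random block, a trended robust variance, array weights, each array and each replicate number left out, KNOX-18 or Col wet replicate 3 left out, and stricter thresholds (adjusted p of 0.01, or a log2 difference of 1). Added after seeing the data were SQ-8 left out, each replicate number alone, and a covariate made from clock genes.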

Results

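Leaf transcript levels were compared between well watered and slowly dried plants of 10 spring annual accessions of Arabidopsis, with 3 arrays per accession and watering level and 2 for KNOX-18 dry. The 59 arrays gave log2 values for 20728 loci, and array medians ranged from 5.496 to 5.621. Of the variation of a gene across arrays, a mean of 28.8% lay between accessions, 7.18% between watering levels, 12.7% in their interaction, 9.03% between replicate numbers and 42.4% among the remaining differences within groups. These shares take no account of degrees of freedom (1 for watering, 9 for the interaction) and so do not rank the effects. Errors given with log2 differences of genes are standard errors (SE) of the limma fit. Those of list shifts come from the spread of the list means over the arrays of each group.

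The first comparison asked which genes changed with mild soil drying on average over the 10 accessions (30 wet and 29 dry arrays). The largest rises were those of LTP4 and LTP3, which encode lipid transfer proteins, HIS1-3, a drought-inducible linker histone, and BGLU18, a beta-glucosidase that can release ABA from its glucose ester. LTP4 rose by 3.27 ± 0.32 on the log2 scale, a 9.65-fold change (limma adjusted p = 4.08e-10), and LTP3 by 2.92 ± 0.48 (adjusted p = 8.4e-06). HIS1-3 rose by 2.69 ± 0.17 (adjusted p = 8.92e-15) and BGLU18 by 2.67 ± 0.39 (adjusted p = 1.4e-06). The falls were led by GASA1, a gibberellin-regulated peptide gene, AZI1, a lipid transfer-like gene tied to azelaic acid priming, and ERD5, which encodes the proline dehydrogenase that breaks proline down. GASA1 fell by 2.81 ± 0.25 (adjusted p = 4.01e-11), AZI1 by 2.51 ± 0.28 (adjusted p = 7.79e-09) and ERD5 fell by 2.45 ± 0.18 (adjusted p = 3.62e-13).

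Among genes with 1 sign in all 10 accessions, to which both sets were limited, the other 6 largest rises were AT3G53980 (2.62 ± 0.22), AT3G28220 (2.44 ± 0.37), AT2G37870 (2.31 ± 0.25), AT1G73480 (2.02 ± 0.27), COR15B (1.88 ± 0.33), which encodes a chloroplast protein of cold and dehydration tolerance, and the dehydrin gene RAB18 (1.79 ± 0.14). Under the same limit the remaining falls were AT1G22690 (-2.21 ± 0.19), AT3G16670 (-2.18 ± 0.30), the cytosolic glutamine synthetase gene GLN1;4 (-2.15 ± 0.29), AT5G64120 (-2.09 ± 0.19), the xyloglucan endotransglucosylase gene XTH7 (-2.08 ± 0.24), AT1G62480 (-2.06 ± 0.24) and AT2G43620 (-1.97 ± 0.18). RAB18 had a wet mean of 4.54, near the bottom of the scale, so its rise is a lower limit and its rank is not exact. Adjusted p-values of these genes ran from 4.11e-12 for RAB18 to 2.63e-05 for COR15B. LTP3 and LTP4 are close copies whose values correlated at r = 0.912 over the arrays, so signal shared between their probes cannot be excluded and they are uncertain as separate genes.

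In all, 6069 genes (29.3%) passed the threshold for drying, 3205 of them higher and 2864 lower in dry leaves. The share that was higher was 52.8% as deposited, 48.6% with array medians centred and 50.1% with quantile normalization, so the majority direction depends on scaling. The changes were small for most: the median size was 0.283 on the log2 scale, and 200 genes (113 higher, 87 lower) reached a log2 difference of 1. Of the 6069 genes, 2173 (35.8%) had the same sign in all 10 accessions. Since these genes were chosen by their mean over the accessions, this share has no chance value here. Fitting each replicate number alone gave 4028, 3654 and 792 genes for numbers 1, 2 and 3, and a score of morning minus evening clock genes, which differed between the numbers, was lower in dry than in wet leaves by a mean of -0.463 (SD 0.41) in 9 of 10 accessions (exact sign-flip p = 0.00977).

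Among dehydration and ABA induced genes, 18 of 29 measured members rose and 2 fell (18 and 3 adjusted over the list alone). Besides LTP4, LTP3, COR15B and RAB18, the homeobox gene HB-7 rose by 1.58 ± 0.14, COR15A by 1.52 ± 0.18, the transcription factor gene DREB2A by 1.39 ± 0.25 and the dehydrin gene LTI30 by 1.34 ± 0.23. HAI1, a clade A protein phosphatase gene, rose by 0.64 ± 0.10 (adjusted p = 2.67e-06) and NCED3, which encodes a rate-limiting enzyme of ABA synthesis, by 0.43 ± 0.13 (adjusted p = 0.0133). HAI1 lay near the bottom of the scale, so its rise is a lower limit. ERD1 fell by 0.48 ± 0.09 and ERD14 fell by 0.33 ± 0.09. RD29A, named LTI78 in the reference table, differed by 0.24 ± 0.27 and did not pass (adjusted p = 0.568). RD29B, named LTI65, differed by 0.12 ± 0.04 (adjusted p = 0.0311), a call that was lost with array medians centred (0.11) or without NFA-10 wet 1 (0.11), Col dry 1 (0.11), Col wet 2 (0.11) or KNOX-18 dry 3 (0.09). The list passed camera (adjusted p = 3.54e-07, and adjusted p = 0.0369 with an estimated correlation), and its mean rose in 10 of 10 accessions (exact sign-flip adjusted p = 0.00732).

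Cytokinin response genes rose as a group, 12 of 15 measured members higher and 0 lower, with the same 12 adjusted over the list alone. The type A response regulator genes ARR7 (1.42 ± 0.16), RR5 (1.38 ± 0.17), ARR9 (1.31 ± 0.19) and ARR4 (1.21 ± 0.12) moved most, and the cytokinin oxidase gene CKX4 rose by 0.70 ± 0.06. The list passed camera (adjusted p = 1.83e-08, and adjusted p = 0.0315 with an estimated correlation) and its mean was higher in 10 of 10 accessions (exact sign-flip adjusted p = 0.00732). In Ler alone this rise was smaller than its SE (0.186 ± 0.316). The cytokinin list was one of 2 lists, with the dehydration list, whose camera call held with an estimated correlation, although with the replicate number as a block these adjusted p-values were 0.0746 and 0.118.

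Many photosynthetic genes rose by small amounts. In the Calvin cycle list 10 of 13 members rose and 0 fell (10 and 0 adjusted over the list alone), among them GAPB (0.53 ± 0.13), the fructose bisphosphatase gene HCEF1 (0.52 ± 0.11) and RPE (0.44 ± 0.07). The list passed camera (adjusted p = 2.61e-05), its call was lost with the estimated value (adjusted p = 0.321 with an estimated correlation), and its mean rose in 10 of 10 accessions (exact sign-flip adjusted p = 0.00732). This rise was smaller than its SE in Col (0.0375 ± 0.253), Ts-1 (0.0582 ± 0.142), Ws-2 (0.092 ± 0.196), SQ-8 (0.221 ± 0.245) and HR-5 (0.289 ± 0.295), and larger in the others. In the photosynthesis and light harvesting list 13 of 21 rose and 0 fell (13 and 0 adjusted over the list alone), led by the oxygen-evolving complex gene PSBO2 (0.72 ± 0.13) and the plastocyanin gene PETE1 (0.47 ± 0.08). It also passed camera (adjusted p = 5.22e-05, and adjusted p = 0.631 with an estimated correlation), with its mean higher in 9 of 10 accessions (exact sign-flip adjusted p = 0.0135).

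Jasmonate and wounding genes were higher in dry leaves in 12 of 16 cases and lower in 1 (12 and 1 adjusted over the list alone). The lipoxygenase gene LOX3 rose by 1.33 ± 0.23, and the JAZ repressor genes JAZ5 and JAZ10 by 1.16 ± 0.23 and 0.99 ± 0.20. The defensin gene PDF1.2, which responds to jasmonate together with ethylene, fell by 1.99 ± 0.49 on average, being lower in 8 of 10 accessions. The list passed camera (adjusted p = 2.61e-05, and adjusted p = 0.318 with an estimated correlation), with a higher mean in 9 of 10 accessions (exact sign-flip adjusted p = 0.013). Galactinol, starch and sugar genes rose in 10 of 22 cases and fell in 1 (12 and 1 adjusted over the list alone), with the galactinol synthase gene GolS2 at 0.71 ± 0.19 and the starch degradation genes SEX1 and DPE1 at 0.80 ± 0.18 and 0.79 ± 0.24. This list's camera call (adjusted p = 0.0304) was lost with the estimated value (adjusted p = 0.164 with an estimated correlation), with dim loci left out (adjusted p = 0.16), without KNOX-18 wet 2 (adjusted p = 0.0536) and without Ler wet 3 (adjusted p = 0.0612), while its mean rose in 10 of 10 accessions (exact sign-flip adjusted p = 0.00732). That rise was smaller than its SE in SQ-8 (0.0136 ± 0.175), CIBC-17 (0.0237 ± 0.106) and Ts-1 (0.117 ± 0.142), and larger in the others.

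Of the cold and CBF regulon genes 0 of 13 were higher and 4 lower, 9 not being called (0 and 4 adjusted over the list alone). RAV1 fell by 0.55 ± 0.10 and BAP1 fell by 0.44 ± 0.08, while CBF1 differed by -0.20 ± 0.29 and DREB1A by 0.28 ± 0.23 without passing. The camera adjusted p was 0.0262 (adjusted p = 0.164 with an estimated correlation), and the mean was lower in 9 of 10 accessions (exact sign-flip adjusted p = 0.0135). COR15A and COR15B, whose rises are given above, were placed in the dehydration list and not in this one. The direction of the cold list therefore depends on how members were split between the lists, and holds for these 13 alone. Circadian clock genes passed camera only with the replicate number as a block (adjusted p = 0.147 without and 0.0368 with it; adjusted p = 0.579 with an estimated correlation). ELF3, whose values lie low on the scale, rose by 0.47 ± 0.13, and 2 of 11 members were higher (1 adjusted over the list alone). The mean of the clock list was higher in 10 of 10 accessions (exact sign-flip adjusted p = 0.00732), but with replicate number 1 alone the shift was reversed, at -0.00654. With all arrays the shift was smaller than its SE in CIBC-17 (0.015 ± 0.0988), Col (0.0947 ± 0.206), KNOX-18 (0.162 ± 0.226) and SQ-8 (0.198 ± 0.203).

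Of the 30 lists, 7 passed camera, 2 with an estimated correlation and 8 with the replicate number as a block. As many lists passed in 35 of 100 splits of the wet and dry arrays within accessions, the real one included, so the number of lists by itself does not exceed chance. Among the other splits up to 13 lists passed. A camera call of an individual list at the preset correlation therefore does not by itself show that the list changed with drying. How often each list passed in the splits is not given here. The exact sign-flip test, which takes the accession as its unit, passed 15 of the 30.

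Several lists that did not pass camera held changes in both directions. In ABA core signalling 9 of 24 members rose and 6 fell (9 and 6 adjusted over the list alone; camera adjusted p = 0.402): the receptor genes PYL4, PYL5 and PYL6 fell by 1.42 ± 0.23, 1.16 ± 0.11 and 0.76 ± 0.11, and the phosphatase genes PP2CA and HAI2 rose by 1.31 ± 0.08 and 0.84 ± 0.08, the latter a lower limit from a wet mean of 3.84, near the bottom of the scale. Among expansins and cell wall genes 7 of 23 rose and 8 fell (7 and 10 adjusted over the list alone; camera adjusted p = 0.564), with XTH24 (-1.45 ± 0.12) and XTH9 (-1.41 ± 0.23) lower and the expansin genes EXPA1 (1.24 ± 0.18) and EXPA10 (0.95 ± 0.09) higher. The median of that list was 0.0463 and its mean -0.196, so the signs of the median and of the test differ. The mean was lower in 10 of 10 accessions (exact sign-flip adjusted p = 0.00732). However, the shift was smaller than its SE in NFA-10 (-0.0067 ± 0.449), Bur-0 (-0.0213 ± 0.273), Ts-1 (-0.025 ± 0.243), Col (-0.0518 ± 0.146), CIBC-17 (-0.0689 ± 0.296) and KNOX-18 (-0.409 ± 0.54). It exceeded its SE in Ws-2, HR-5, SQ-8 and Ler. Reactive oxygen scavenging genes went both ways, 4 of 16 higher and 4 lower (5 and 4 adjusted over the list alone; camera adjusted p = 0.944). The copper/zinc superoxide dismutase genes CSD1 and CSD2 fell by 1.34 ± 0.23 and 1.55 ± 0.26, and the iron superoxide dismutase gene FSD1 rose by 1.51 ± 0.23.

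In proline metabolism 1 of 5 members rose and 2 fell (1 and 4 adjusted over the list alone, camera adjusted p = 0.0685). The mean of the list was lower in 10 of 10 accessions (exact sign-flip adjusted p = 0.00732). That mean shift of -0.525 was carried largely by ERD5, whose fall is given above, while the median over members was -0.228. Besides ERD5 the regulator gene BZIP53 fell by 0.42 ± 0.08, while ALDH12A1 rose by 0.68 ± 0.13. Nitrogen and amino acid genes split evenly, 4 of 15 higher and 4 lower (6 and 4 adjusted over the list alone; camera adjusted p = 0.88), with the nitrate transporter gene NRT1.1 at -1.39 ± 0.19 and the nitrite reductase gene NIR1 at 0.59 ± 0.09. Of 17 glucosinolate synthesis genes 8 rose and 2 fell (10 and 2 adjusted over the list alone; camera adjusted p = 0.0685), including MYB29 (0.61 ± 0.12), CYP79B3 (0.87 ± 0.22) and MYB51 (-0.62 ± 0.12). That list passed with array medians centred (adjusted p = 0.0403) and without any 1 of 7 arrays: Ler wet 1 (0.0426), Col wet 1 (0.0346), Ler wet 2 (0.0256), Col dry 2 (0.031), HR-5 wet 3 (0.0433), KNOX-18 wet 3 (0.0334) or NFA-10 wet 3 (0.0448).

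Aquaporins gave 2 of 13 higher and 3 lower (2 and 4 adjusted over the list alone; camera adjusted p = 0.32), with the tonoplast gene GAMMA-TIP at -1.26 ± 0.15 and PIP1;5 at -0.82 ± 0.17. The mean was lower in 9 of 10 accessions (exact sign-flip adjusted p = 0.043), but with replicate number 1 alone the shift was reversed, at 0.16. Auxin response genes gave 4 of 20 higher and 1 lower (6 and 2 adjusted over the list alone; camera adjusted p = 0.402), with AXR3 at -1.02 ± 0.18 and IAA14 at 0.75 ± 0.09. Gibberellin and brassinosteroid genes gave 4 of 19 higher and 2 lower (5 and 2 adjusted over the list alone; camera adjusted p = 0.944), with GASA4 at 1.16 ± 0.28 against the fall of GASA1. In the cell cycle list 2 of 15 were higher and 4 lower (2 and 5 adjusted over the list alone; camera adjusted p = 0.136): the D-type cyclin gene CYCD3;1 rose by 1.22 ± 0.18 and the histone gene HTA6 fell by 1.13 ± 0.15. Leaf senescence genes were mostly not called, 1 of 16 higher and 3 lower (1 and 3 adjusted over the list alone; camera adjusted p = 0.455), with WRKY53 at -0.54 ± 0.12 and SAG20 at -0.48 ± 0.08. Salicylate defence genes gave 0 of 20 higher and 2 lower (0 and 2 adjusted over the list alone; camera adjusted p = 0.224), and PR1 differed by 0.17 ± 0.30 (adjusted p = 0.728). Heat shock protein genes gave 1 of 15 higher and 0 lower (1 and 0 adjusted over the list alone), with HSP70 at 0.86 ± 0.27. Their camera adjusted p was 0.455, and 0.0201 without Bur-0 wet 1. Flavonoid and anthocyanin genes gave 1 of 17 higher and 1 lower (0 and 0 adjusted over the list alone; camera adjusted p = 0.944).

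Markers of other organs and cell types were measured for the makeup of the leaf samples. Guard cell markers gave 2 of 11 higher and 0 lower (2 and 0 adjusted over the list alone; camera adjusted p = 0.515), with the potassium channel gene KAT1, low on the scale, at 0.39 ± 0.09. Vascular markers gave 2 of 13 higher and 2 lower (2 and 2 adjusted over the list alone; camera adjusted p = 0.742), with the proton pump gene HA3 at 0.84 ± 0.14 and XCP1 at -0.23 ± 0.05. Trichome and epidermis markers gave 2 of 13 higher and 5 lower (3 and 5 adjusted over the list alone; camera adjusted p = 0.222), with the wax gene KCS6 at -0.93 ± 0.14 and the epidermal regulator gene ATML1 at -0.46 ± 0.08. Their mean was lower in 9 of 10 accessions (exact sign-flip adjusted p = 0.0135). Root markers gave 0 of 13 higher and 2 lower (0 and 1 adjusted over the list alone; camera adjusted p = 0.112), their mean shift being -0.0769 and lower in 10 of 10 accessions (exact sign-flip adjusted p = 0.00732). Floral markers gave 1 of 12 higher and 1 lower (1 and 1 adjusted over the list alone, camera adjusted p = 0.595), with AGL8 at 0.40 ± 0.05 and a mean higher in 9 of 10 accessions (exact sign-flip adjusted p = 0.0377). The means of the root and floral lists lay low on the scale on every array. Their small shifts may be a drift of the background and say little about the makeup of the samples. Housekeeping genes gave 0 of 8 higher and 3 lower (0 and 3 adjusted over the list alone; camera adjusted p = 0.112), ACT2 differing by -0.22 ± 0.04 and the mean being lower in 9 of 10 accessions (exact sign-flip adjusted p = 0.0135). Cytosolic ribosomal protein genes gave 1 of 6 higher and 0 lower (1 and 0 adjusted over the list alone; camera adjusted p = 0.515). The known natural variation list gave 2 of 22 higher and 2 lower (2 and 2 adjusted over the list alone; camera adjusted p = 0.779), with the receptor kinase gene ER at 0.64 ± 0.10.

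**Figure D1:**
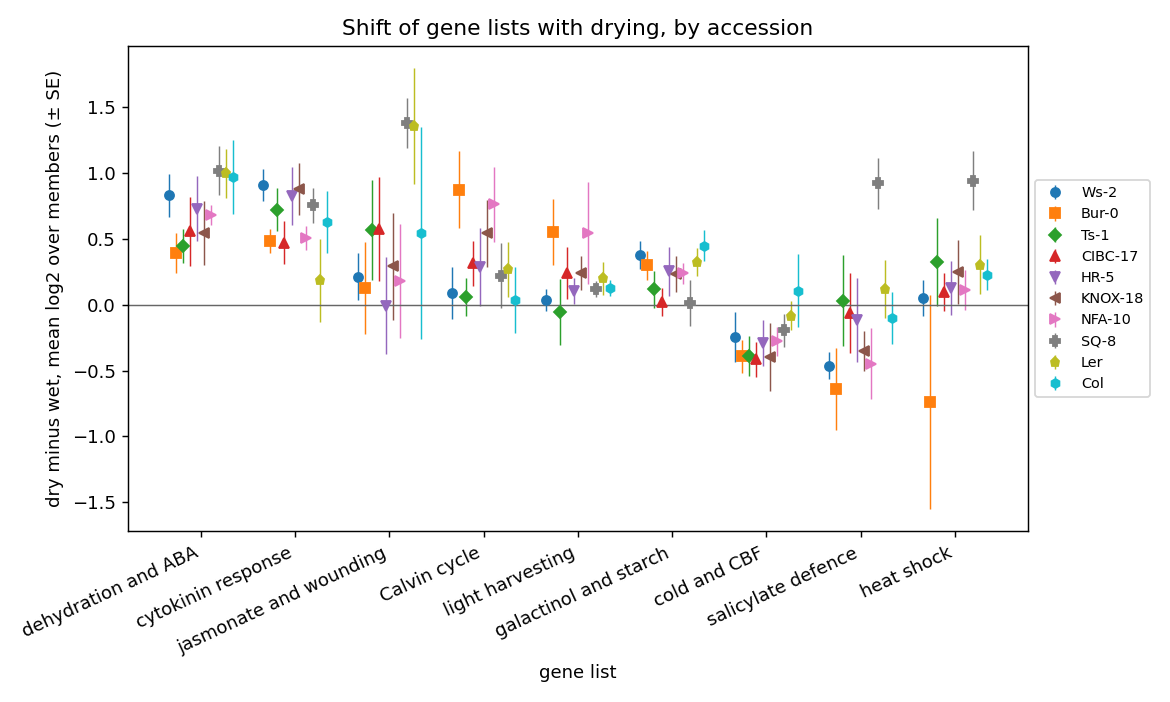
Dry minus wet of the mean log2 value of 9 gene lists (vertical axis, log2), each list on the horizontal axis with 1 marker per accession; bars are SE over arrays. The dehydration and cytokinin lists lay above 0 in all 10 accessions, and the salicylate list reached 0.923 in SQ-8 and -0.64 in Bur-0.

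The next comparison took each accession by itself, 3 dry against 3 wet arrays (2 dry for KNOX-18). The limma fit called 1025 genes in SQ-8 (538 higher, 487 lower), 563 in Bur-0 (361 and 202), 182 in Ws-2, 146 in Ler, 135 in HR-5, 126 in Col, 76 in Ts-1, 32 in NFA-10, 27 in KNOX-18 and 13 in CIBC-17. In SQ-8 the jasmonate genes LOX3 (3.40, adjusted p = 0.00331) and JAZ10 (3.36, adjusted p = 0.00102), the salicylate marker PR1 (3.27, adjusted p = 0.0339) and the heat shock genes HSP17.6A (2.67, adjusted p = 0.0114) and AT5G48570 (2.66, adjusted p = 0.000735) rose. The wet means of JAZ10 (4.46), HSP17.6A (3.64) and AT5G48570 (4.42) were near the bottom of the scale, so these 3 rises are lower limits. EDS1, a regulator of salicylate defence, rose there by 1.48 (adjusted p = 0.0115). These genes did not pass the interaction test (adjusted p from 0.231 for AT5G48570 to 0.737 for PR1), so their rises are not shown to be particular to SQ-8. The jasmonate list shifted by 1.38 in SQ-8 and by 1.36 in Ler. With the replicate number as a block the counts were 1803 in SQ-8, 1074 in Bur-0, 539 in Ws-2, 330 in Ler, 393 in HR-5, 312 in Col, 203 in Ts-1, 383 in NFA-10, 85 in KNOX-18 and 38 in CIBC-17. Without the block, leaving out 1 array moved the counts to between 325 and 1273 in SQ-8, 44 and 696 in Bur-0, 34 and 219 in Ws-2, and 28 and 252 in Ler. The ranges were 28 to 199 in HR-5, 30 to 172 in Col, 23 to 128 in Ts-1, 4 to 644 in NFA-10, 13 to 47 in KNOX-18 and 4 to 22 in CIBC-17. The 644 in NFA-10 came without NFA-10 wet 3.

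**Figure D2:**
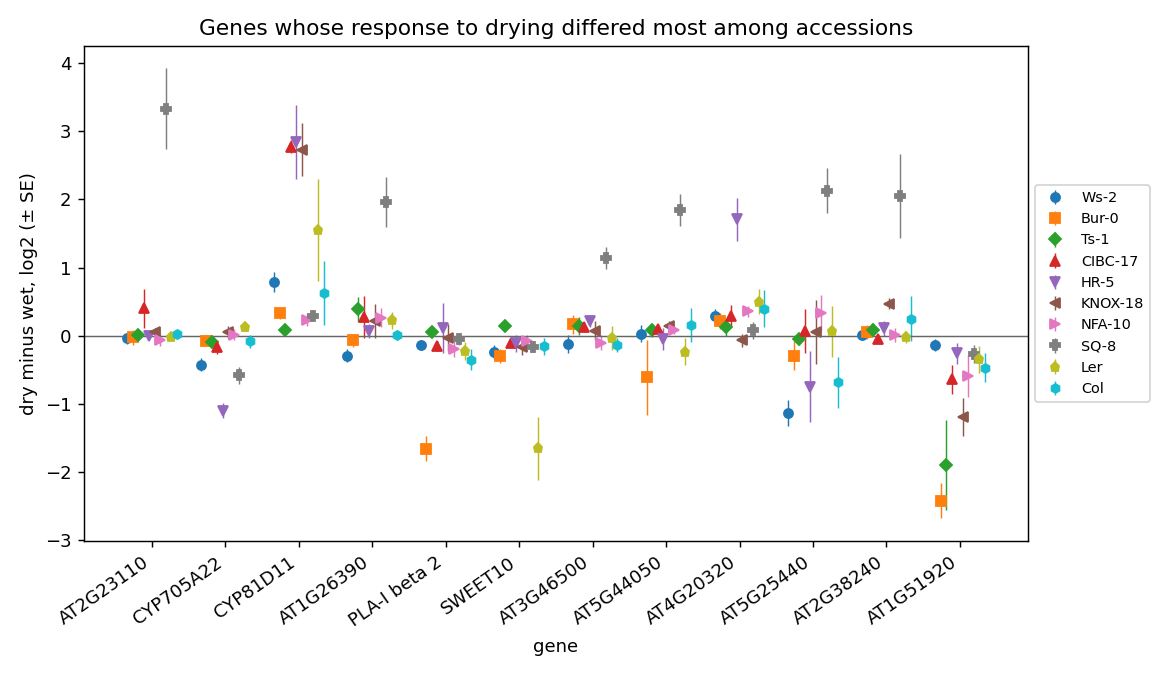
Dry minus wet (vertical axis, log2, with SE from the arrays of each group) in each of the 10 accessions for the 12 genes with the smallest interaction p (horizontal axis). SQ-8 stood apart in AT2G23110 at 3.33, and HR-5, CIBC-17 and KNOX-18 in CYP81D11 at 2.84, 2.78 and 2.73, followed by Ler at 1.55.

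Whether the response to drying differed among accessions was tested with the interaction. AT2G23110 rose by 3.33 in SQ-8 and lay between -0.06 and 0.40 in the other 9 accessions (limma interaction adjusted p = 4.39e-09, SE 0.22 for an accession with 3 arrays per level). CYP81D11, a cytochrome P450 gene, rose by 2.84 in HR-5, 2.78 in CIBC-17, 2.73 in KNOX-18 and 1.55 in Ler and differed by 0.08 to 0.79 in the other 6 without passing (adjusted p = 0.000131, SE 0.34). CYP705A22, another P450 gene, fell in HR-5 (adjusted p = 2.52e-10), by 0.58 in SQ-8 and by 0.42 in Ws-2 (interaction adjusted p = 1.35e-06, SE 0.09). SQ-8 also stood highest in AT5G25440 (2.13, against -1.14 in Ws-2), AT2G38240 (2.06), AT1G26390 (1.96), AT5G44050 (1.85) and AT3G46500 (1.14). The fit shares 1 spread over all groups. The SD of the SQ-8 dry arrays was larger, at 0.96 for AT2G23110, 1.06 for AT2G38240 and 0.64 for AT1G26390. For these genes the SE and the interaction p therefore understate the spread within SQ-8. In Bur-0, AT1G51920 fell by 2.43 and PLA-I{beta]2, a phospholipase gene, by 1.66. AT1G51920 fell by 1.90 in Ts-1 as well. The sugar transporter gene SWEET10 fell by 1.66 in Ler, and AT4G20320 rose by 1.71 in HR-5. Apart from AT5G25440 and AT1G51920, these genes lay near the bottom of the scale in most accessions (AT2G23110 between 3.91 and 4.47 in all wet groups), so their differences are lower limits.

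In all 56 genes passed the interaction test, 97 with the replicate number as a block, all 56 kept among them. It was 29 with dim loci left out and 89 with KNOX-18 left out. At an unadjusted p under 0.05 there were 1758 genes (8.48%). SQ-8 had the response farthest from the mean of all accessions in 31 of the 56 genes and Bur-0 in 11. Over all genes the shares were 21.8% for SQ-8 and 14.4% for Bur-0. The count was 36 without SQ-8 wet 1, 28 without SQ-8 wet 3, 34 without SQ-8 dry 3 and 12 with SQ-8 left out. For lists, 0 of 30 passed the permutation test of the interaction, and 3 lay under an unadjusted permutation p of 0.05: salicylate defence (0.0085), glucosinolate synthesis (0.0107) and leaf senescence (0.0157), all with an adjusted p of 0.157. The salicylate list shifted by 0.923 in SQ-8 and by -0.64 in Bur-0, and the glucosinolate list by 1.02 in Col and -0.512 in SQ-8.

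Across genes, dry minus wet correlated between accessions at a mean r of 0.511 over the 45 pairs (SD 0.122; Spearman mean 0.384), genes not being independent replicates. The lowest pair was SQ-8 with Bur-0 (r = 0.0986) and the highest reached 0.708. SQ-8 had the lowest mean r with the other accessions (0.385), and KNOX-18 the highest (0.574).

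Differences among accessions, averaged over the watering levels, reached larger sizes than those of drying. FLC, a floral repressor gene of vernalization, stood at 10.59 in Ts-1, 9.21 in CIBC-17 and 8.45 in Bur-0 and near the bottom of the scale in Ws-2 (4.09), Ler (4.11), Col (4.33) and SQ-8 (4.38), a range of at least 6.50 (SE of an accession mean 0.14, limma adjusted p = 1.16e-30). ESM1, which modifies glucosinolate hydrolysis, stood at 12.06 in Col and between 6.32 and 9.16 in the other 9 (SE 0.30, adjusted p = 1.73e-12). ESP, the epithiospecifier gene of the same pathway, stood at 7.22 in Col and between 12.29 and 12.89 elsewhere (SE 0.16, adjusted p = 4.02e-23). RPP4, a downy mildew resistance gene, stood at 6.74 in Col and between 3.36 and 3.43, near the bottom of the scale, elsewhere (SE 0.05, adjusted p = 2.19e-35).

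**Figure D3:**
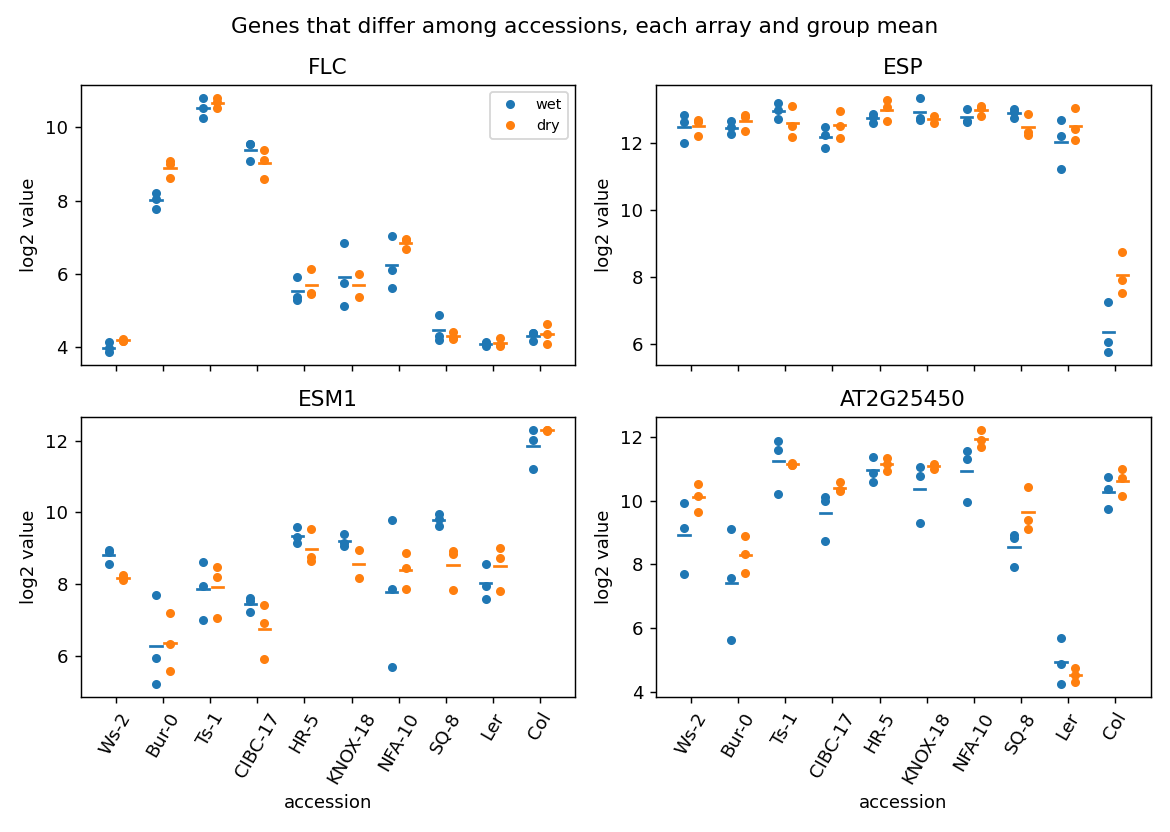
Log2 values (vertical axes) of FLC, ESP, ESM1 and AT2G25450 on each array, by accession (horizontal axes) and watering level; horizontal bars are group means. FLC reached 10.59 in Ts-1, Col was lowest in ESP at 7.22 and highest in ESM1 at 12.06, and AT2G25450 was lowest in Ler at 4.73.

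For most genes in this paragraph the low values lie near the bottom of the scale, where they cannot be told from background, so the ranges are lower limits and their order is not exact. AT2G25510 ranged over at least 8.70, from 4.72 in Ler and 5.10 in KNOX-18 to 13.42 in CIBC-17. AT2G25450 ranged over at least 6.71 with Ler lowest at 4.73 and NFA-10 and Ts-1 high at 11.44 and 11.19, the basic chitinase gene HCHIB over at least 6.66 with Bur-0 highest at 11.01, and AT3G48640 over at least 6.63 with Col lowest at 4.39. PDF1.2 ranged over at least 6.55 with an SE of 0.78, highest in Bur-0 at 11.05. AT2G15555 was high in Ws-2 (11.17, range at least 6.44), AT5G15360 was low in Col (range at least 6.15, the other 9 between 9.33 and 10.25) and ECS1 was high in Col (11.44, range 6.08). DR4 was low in CIBC-17, Bur-0 and Col (4.66, 4.70 and 5.37, SE 0.30), with a range of at least 6.38. AT1G50290 was low in Ts-1, SQ-8, Bur-0 and Col (4.40, 4.62, 5.42 and 6.29, SE 0.16), with a range of at least 5.94. PHYD, a phytochrome gene, was highest in Bur-0 at 7.54, with Ws-2 (5.85), SQ-8 (5.93) and HR-5 (5.94) low (SE 0.11, adjusted p = 5.9e-12). PR1 ranged over 3.35 (adjusted p = 0.000255), with 9.38 in Bur-0 and 6.19 in Ws-2. Its mean of 9.54 in SQ-8 joins 7.90 in wet and 11.17 in dry leaves, so it is carried by the dry arrays. A low value in an accession other than Col can be a lower transcript level or a poorer match to the probe; these were not told apart here.

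The accession test called 8565 genes (41.3%). Among the lists, 17 of 20 salicylate defence genes, 16 of 22 known natural variation genes, 15 of 17 glucosinolate synthesis genes and 10 of 29 dehydration and ABA induced genes differed among accessions. The counts with each replicate number alone were 1310, 2153 and 549 genes.

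Against Col, whose genome is the reference, the 9 other accessions gave 19445 calls, summed over accessions, all of them sharing the same 6 Col arrays, so the 9 counts are not independent. Of these calls 11486 (59.1%) were higher than in Col and 7959 lower. With array medians centred 48.2% were higher, and with quantile normalization 53.2%. Bur-0 differed most, with 2441 genes higher and 1675 lower, followed by HR-5 (1721 and 1104), NFA-10 (1587 and 1072) and Ler (1575 and 899). CIBC-17 had 1276 higher and 802 lower, Ts-1 1033 and 886, SQ-8 766 and 599, Ws-2 550 and 467, and KNOX-18 537 and 455. By 2 or more on the log2 scale, lower calls outnumbered higher ones in all accessions but SQ-8 (36 higher, 27 lower). There were 50 genes higher and 62 lower in Bur-0, 24 and 49 in HR-5, and 21 and 24 in KNOX-18.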

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

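Chosen only after the result was seen were the tests of the identity of the SQ-8 arrays, of exchanged wet and dry labels in SQ-8 and of the salicylate interaction, the tests of probe mismatches and of array scaling against Col, and the fits with a clock covariate or with SQ-8 left out.

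The response to drying differed among accessions, by the limma interaction test, for the 12 genes with the smallest p. The range of dry minus wet over the 10 accessions was 3.39 for AT2G23110, 3.27 for AT5G25440, 2.76 for CYP81D11, 2.46 for AT5G44050, 2.29 for AT1G51920, 2.25 for AT1G26390 and 2.11 for AT2G38240. It was 1.79 for SWEET10, 1.78 for PLA-I{beta]2, 1.78 for AT4G20320, 1.28 for AT3G46500 and 1.22 for CYP705A22. Apart from AT5G25440 and AT1G51920, these genes lay near the bottom of the scale in most accessions, so their ranges are lower limits. With SQ-8 left out the interaction was lost for 6 of the 12. The spread shared by the test is smaller than that of the SQ-8 dry arrays for AT2G23110, AT2G38240 and AT1G26390.

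SQ-8 stands apart: its response lay farthest from the mean in 31 of 56 interaction genes (against 21.8% of all genes), and its salicylate list shifted by 0.923 (SE 0.194), the other 9 lying between -0.64 and 0.121. Single arrays of another accession are argued against, since 6 of 6 SQ-8 arrays lay nearest to SQ-8 over the 300 genes that separate accessions best (all 6 coming from another source would pass this too and is left open), and exchanged watering labels are argued against by the dehydration list, which shifted upward in SQ-8 by 1.02 (SE 0.186). For the salicylate shift a single dry array is not the source either: with 1 dry array left out it stayed between 0.854 and 1.01. The count of interaction genes did depend on single SQ-8 arrays, being 34 without SQ-8 dry 3 and 28 without SQ-8 wet 3. For those genes a part played by single arrays stays open. A response to drying particular to SQ-8 remains a hypothesis, because the salicylate list's own interaction reached a permutation adjusted p of 0.157, which neither shows nor excludes it. Infection or another stress of the SQ-8 dry plants may account for it as well and was not tested.

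Against Col, 59.1% of calls were higher than Col, where mismatches to the probes, if these were designed on Col, would make the others lower. Among genes in which 1 accession other than Col stood at least 2 log2 units from all others, 46.4% (13 of 28) were lows (exact 95% interval 27.5 to 66.1), which decides nothing about mismatches. The excess of higher over lower calls was 3527 with Col as the comparator and between -2055 and 1049 with the other 9, beyond what was set in advance as the range of chance. That bound took the array medians as comparable, and with medians centred Col lay inside the others (-686, against -1412 to 2313), so a chance level of the Col arrays cannot be told apart from a real excess. Array scaling may be the source, with 48.2% higher after centring medians, but quantile normalization left 53.2% and an excess of 1209 above the highest other of 777, so it stays open.

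Over all arrays together, 6223 genes differed by replicate number. Array brightness or scaling is argued against, since 6292 genes differed after quantile normalization. Morning clock genes (CCA1, LHY and RVE8) minus evening ones (TOC1, PRR5, GI and ELF4) were lower in number 3 than in number 1 by a mean of -3.64 (SD 0.799) in 20 of 20 groups, which is consistent with harvest at another time of day, although the labels give no hour and anything else shared by a number stays open. Dry leaves were also lower in this score than wet ones. With the score as a covariate 6554 genes differed, 5849 of them among the 6069. The 20 genes with the largest changes kept 105% of their median size, so an effect linear in this score does not account for them. They were chosen for large changes of 1 sign, so this need not hold for other genes. The score follows the replicate number, and a block for that number also raised the count, to 7083. The count therefore cannot decide, and a different hour of harvest as a source of part of the drying result stays open.

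Whether chance groupings of the arrays give results as large was counted over 100 splits, the real one included. For drying, the real split alone (1 of 100) reached 6069 genes, the highest other giving 1589, and among splits that part every same-numbered wet and dry pair it was again 1 of 100, the highest other giving 485. The real split was 1 of 100 for the accession effect (8565 genes, highest other 22) and for the interaction (56, highest other 3). It was also 1 of 100 for calls against Col (19445, highest other 738). These counts were not reached by any other split, although 100 splits cannot show a share below 1 of 100. Regrouping also puts real differences into the spread within groups, which lowers the counts of the other splits. Conditions shared by all arrays of a group were not tested by it. The number of lists passing camera was reached by many splits. For it 35 of 100 gave 7 or more (highest other 13), and 31 of 100 when pairs were parted (highest other 15). Camera calls of individual lists at the preset correlation are limited by this as well. Within an accession 10 splits exist, too few for a share under 0.05. There the real split was 1 of 10, with real counts and highest others of 182 and 1 in Ws-2, 563 and 8 in Bur-0, 76 and 4 in Ts-1, 13 and 2 in CIBC-17, 135 and 5 in HR-5, 27 and 5 in KNOX-18, 1025 and 7 in SQ-8, 146 and 19 in Ler, and 126 and 7 in Col. In NFA-10 2 of 10 splits reached the real 32; the other one gave 35 and set both arrays of number 1 against both of number 3, and the count with the replicate number as a block was 383.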

How the results depend on the processing

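Fits with SQ-8 left out, with 1 replicate number alone and with the clock covariate were chosen after seeing the data. Counts stayed within 1.5 times of their values under both scalings, a trended robust variance, without Col wet 3 and, except as given here, under all other settings; where they did not, the cause was not tested unless fewer arrays or genes or a stricter threshold is the setting itself. With the replicate number as a block, calls within accessions rose from 2325 to 5160 and interaction genes from 56 to 97 (random block: 3898 and 91); of the lists, circadian clock alone changed its camera call at the preset correlation, while with an estimated correlation the calls of the dehydration (0.118) and cytokinin (0.0746) lists were lost, and drying calls of 6068 of 6069 genes were kept. Array weights, whose estimation did not converge, gave 13228 calls within accessions, 12900 accession genes, 1407 interaction genes and 32182 calls against Col. Interaction genes were 29 without dim loci, 89 without KNOX-18 and 12 without SQ-8, which also left 1097 calls within accessions. At an adjusted p of 0.01 there were 587 calls within accessions, 14 interaction genes and 9905 calls against Col. With a log2 difference of 1 there were 200 drying genes, 995 calls within accessions, 2361 accession genes and 3638 calls against Col. The clock covariate gave 4009 calls within accessions, Spearman a mean similarity of 0.384, an estimated correlation 2 lists and fry 13.

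Replicate numbers 1, 2 and 3 alone gave 4028, 3654 and 792 drying genes and 1310, 2153 and 549 accession genes. Numbers 2 and 3 gave 11 and 12 camera lists, and numbers 1 and 3 gave 7 and 8 lists by the sign-flip test. Reversed were, in number 1 alone, P40 (-0.0338), RPSAb (-0.31), PIP2A (0.15), PRR3 (-0.0734) and the shifts of the aquaporin (0.16) and circadian lists (-0.00654), in number 2 alone SAG29 (-0.0161), and in number 3 alone AT2G25450 (-0.25) and MYB11 (0.00405).

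Leaving out 1 array or 1 replicate number gave 2975 to 6562 drying genes, 266 to 3012 calls within accessions, 2824 to 8961 accession genes, 7 to 77 interaction genes, 5556 to 22386 calls against Col and 6 to 9 camera lists. Leaving out 1 replicate number gave 11 to 15 sign-flip lists and a mean similarity of 0.405 to 0.486, for which no single arrays were left out. Interaction genes were 36, 28 and 34 without SQ-8 wet 1, wet 3 and dry 3. Lists were not fitted with a random block, since camera takes none. Signal over background was not used here, so dim loci are limited by it to an unknown extent.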

Other observations

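The copper test described here was chosen after CSD1, CSD2 and FSD1 had been seen, with its gene lists and threshold written before its own result.

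The sub-groups of lists described next were formed after the values were seen, and no difference between them was tested. In the ABA core list, of the receptor genes PYL4, PYL5, PYL6, PYL1 (-0.61 ± 0.12), PYR1 (-0.50 ± 0.12) and RCAR3 (-0.45 ± 0.10) fell, while PYL7 rose by 0.56 ± 0.11 and RCAR1 (-0.15 ± 0.12) and PYL2 (0.00 ± 0.03) did not pass. Of the phosphatase genes PP2CA, HAI2, ABI2 (0.54 ± 0.07) and ABI1 (0.41 ± 0.08) rose, and HAB1 (0.05 ± 0.16), HAB2 (0.11 ± 0.11), AHG1 (0.04 ± 0.03) and HAI3 (-0.02 ± 0.03) did not pass. The kinase genes SNRK2.3 (0.57 ± 0.16) and OST1 (0.29 ± 0.10) rose, and SNRK2.2 (0.38 ± 0.18) did not pass. In the cell wall list the XTH genes XTH6 (-1.19 ± 0.20), XTH16 (-0.72 ± 0.13) and XTH15 (-0.64 ± 0.21) and XTH4 (-0.91 ± 0.31) fell beside XTH7, XTH24 and XTH9, XTH5 rose by 0.21 ± 0.05, and XTH8 (-0.86 ± 0.36) and TCH4 (0.05 ± 0.13) did not pass. The expansin genes EXPA8 (0.76 ± 0.25), EXPA11 (0.77 ± 0.29), EXPA4 (0.46 ± 0.13) and EXPB3 (0.41 ± 0.12) rose beside EXPA1 and EXPA10, and EXPA5, EXPA6, EXPA15 and EXPA16 did not pass.

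Of the starch degradation genes SEX1, DPE1, SEX4 (0.72 ± 0.19), ISA3 (0.54 ± 0.20) and DPE2 (0.40 ± 0.08) rose, and BAM1 (0.17 ± 0.14), BAM5 (0.06 ± 0.07) and BAM3, named CT-BMY in the reference table (-0.25 ± 0.17), did not pass. Also higher were the galactinol synthase genes GolS1 and GolS2, while GolS3 (-0.12 ± 0.09) did not pass. In nitrogen metabolism NIA1 (0.70 ± 0.19), NIR1 and GLT1 (0.77 ± 0.18), which act in nitrate reduction and glutamate synthesis, rose, and the transporter genes NRT1.1, AMT1;1 (-0.49 ± 0.11) and AMT2 (-0.60 ± 0.15) and the cytosolic glutamine synthetase genes GLN1;4 and GSR 1 (-0.75 ± 0.10) fell, while NIA2 (0.64 ± 0.26), GS2 (0.11 ± 0.09) and NRT2:1 (-0.13 ± 0.07) did not pass.

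The fall of CSD1 and CSD2 with the rise of FSD1 is the exchange of superoxide dismutases known from plants low in copper, and a low copper response in dry leaves is a hypothesis. It was tested on 13 other measured genes, 6 that rise and 7 that fall at low copper. The mean of the first minus that of the second shifted by a mean of 0.36 (SD 0.418; exact sign-flip p = 0.0332), which is consistent with the hypothesis only in part: most of the shift came from 3 of the 7 genes expected to fall (CCS, ARPN and COX5B-1), while the 6 expected to rise went both ways. It was above 0 in 8 of 10 accessions, but Ler (0.000527) among them showed no change and Ts-1 lay at -0.228; Col (0.899), KNOX-18 (0.88), Bur-0 (0.773) and SQ-8 (0.697) carry most of the shift. Among these genes CCS (-0.75 ± 0.25), ARPN (-0.70 ± 0.17) and COX5B-1 (-0.71 ± 0.09) fell and CCH (0.37 ± 0.10) and YSL2 (0.33 ± 0.11) rose, but FRO3 went the other way (-0.46 ± 0.17) and the copper transporter gene COPT2 differed by 0.01 ± 0.13. The other genes expected to fall (LAC2, LAC3, LAC12 and LAC13) had means from 3.70 to 4.75, and ZIP2 of the first set 4.56. These lie low on the scale, where a fall is hard to see, so their small changes decide little. Copper in the leaves was not measured, and the score rests on few genes. Whether CCS, ARPN and COX5B-1 change independently of CSD1 and CSD2, which prompted the test, was not examined. The shift therefore cannot tell low copper from another control shared by these genes.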
